A study of Rattus norvegicus with 6 samples.

How the data were processed

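Total RNA from the livers of 6 male rats was amplified, labelled with Cy3 and hybridised to Agilent 1-colour arrays of 62976 spots, per the labels' protocols. Per the file headers, the authors scanned the arrays and extracted the signals with Agilent Feature Extraction 10.7.1.1 (10.7 in the submitters' processing notes), and the deposited scanner files hold, per spot, a background-subtracted processed signal, median spot and background intensities on a linear scale, and flags of 0 or 1. The deposited value table holds a ratio, each array's processed signal divided by its 75th percentile, on a linear scale and with no centring of genes; this was read from the values, which tracked the scanner signal to within 0.00079 log2 units per array for signals over 100. Its column medians were 0.101, 0.103 and 0.0961 in the corn oil arrays and 0.0955, 0.0971 and 0.0953 in the TCEP arrays. The normalization steps of the authors beyond this are not given in the sources used here.

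From the scanner files, the main values were computed as log2 of the processed signal minus each array's 75th percentile over the 61657 non-control probes. The 1319 control spots were left out and 64 spots with outlier flags, summed over the arrays, were set to missing; 5 saturated spots were kept. A probe was kept when it was well above background on all arrays of at least 1 group, which left 37043 probes. Gene symbols came from a RefSeq table of rat assembly GRCr8, matched through unversioned accessions: 27460 probes matched, among them 27348 of 29123 probes with a curated mRNA accession, and 34197 probes kept the name of the array design. Each name was represented by its probe with the highest mean signal, which gave 27642 names, called genes here, of which 10982 carry a symbol. For 6863 names more than 1 probe was kept; of the 75 measured genes that the text names by symbol 40 had several probes kept, and those of 1, Acsm5, disagreed in direction. The array design names an older rat build, so no coordinates are given.

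Groups came from the treatment label and replicate numbers from the sample titles. The labels speak of 3 animals per group, so replicates were taken as animals. TCEP was compared with corn oil by lmFit and eBayes in limma 3.58.1 (R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Of 32 gene lists fixed before the data were examined, 31 had at least 5 measured members and were tested with camera at a preset correlation of 0.01; fry and camera with an estimated correlation were alternatives. Counts adjusted over the list alone use each list's own members, with no adjustment across lists. Where a probe was not well above background on any array of a group, the fold is a bound: the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own.

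The rule for naming genes, also fixed before the data were examined, took the 12 largest increases and 12 largest decreases among genes past the threshold with groups that did not overlap, a gene symbol and a signal well above background on all arrays of the higher group. It also took from each list up to 4 members past the threshold (6 for CAR and PXR targets), or, where fewer than 2 passed, the 2 brightest members; cell type lists may stand as counts. As 0 genes met the first part, the same rule was applied with an unadjusted p under 0.05, which 513 higher and 326 lower genes met. This criterion, and the naming of members that passed adjusted over the list alone and of further CAR and PXR, acute phase and aryl hydrocarbon receptor members, followed after the values were seen.

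Alternatives set before the data were examined were quantile normalization, median centring, normexp background correction with an offset of 50, the deposited table, no filter on dim probes, a filter on all 6 arrays, the mean over probes, every probe on its own, eBayes with trend and robust, slide as a random block, replicate number as a block, outlier-flagged spots kept, and leaving out each array. The scanner files used here hold no mean signal column, so normexp used the median signal. Per the file headers the arrays lay on 3 slides: corn oil replicates 1 and 3 on slide 1, corn oil replicate 2 on slide 2 and the TCEP arrays on slide 3. Corn oil replicate 2 was scanned 23 days after the others, so scan day as a block equals leaving that array out.

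The fit was tested on simulated data for the same comparison and 27642 genes, with variances drawn from the fitted prior and independent errors. It called 1, 21, 46 and 46 of 50 genes changed by log2 fold changes of 0.5, 1, 2 and 3, and 7 of 27442 unchanged genes. The adjusted threshold depends on how many genes change, and 121 genes were called in the simulation against 0 in the real data. The simulated counts therefore do not give the power for single genes in these arrays. A simulated list of 33 genes shifted by 0.5 was called by camera with either correlation and by fry, and 26 of its members passed adjusted over the list alone. With independent errors the simulated lists hold no correlation between genes. These calls therefore do not give the power or error rate of the list tests on the real lists.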

Results

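Liver RNA of male Sprague-Dawley rats, an outbred laboratory stock, was measured on 1-colour whole-genome arrays in 6 animals. The animals had received either corn oil, the vehicle, or tris(2-chloroethyl) phosphate (TCEP), a chlorinated organophosphate flame retardant, at 400 mg per kg per day. Each group held 3 animals and each animal 1 array. The labels disagree on the length of dosing: the treatment protocol gives 9 weeks, and the design text of the series gives 28 days. Between 57.2% (corn oil replicate 2) and 64.4% (TCEP replicate 1) of the 61657 non-control probes per array were well above background. Across genes, array pairs correlated at 0.9857 to 0.9884 within corn oil, 0.9915 to 0.9928 within TCEP and 0.9876 to 0.9911 between the groups. The corn oil arrays were thus no more alike than arrays of different groups. They lay on slides 1 and 2 and were scanned on different days, while the TCEP arrays shared a slide and a scan day. The correlations therefore do not compare animals alone. The number of arrays, 3 per group, limits the precision: the median standard error of a log2 fold change was 0.145. The comparison asks which liver transcripts differ between dosed and vehicle animals.

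Among genes of drug metabolism that the nuclear receptors CAR and PXR are known to induce, 13 rose with TCEP when adjusted over the list alone. Of 33 measured members, 26 had a higher mean in the TCEP livers, and the median log2 fold change of the list was 0.49. In that adjustment 0 members fell (limma, Benjamini-Hochberg), and over all genes tested 0 members passed. Both measured members of the Cyp2b family and 2 of the 4 measured members of the Cyp3a family, hydroxylases of steroids and drugs, were among the 13. Cyp2b2 rose 2.79-fold, from a mean log2 signal of 5.74 ± 0.66 to 7.22 ± 0.28 (SD, 3 animals per group), and Cyp2b1 rose 1.68-fold. Cyp3a23-3a1 rose 2.43-fold and Cyp3a9 2.20-fold, the latter with a log2 difference of 1.14 ± 0.15 (SE). Cyp2c6v1 rose 1.65-fold, from 8.29 ± 0.04 to 9.02 ± 0.15 (SD, 3 animals per group). Among conjugating enzymes, the glucuronosyltransferase Ugt2b1 rose 3.32-fold and the glutathione transferases Gstm3, Gsta2, Gstm1 and Gsta4 rose 3.65-fold, 1.90-fold, 1.68-fold and 1.44-fold. The export pump Abcc3 had the largest rise of the list, 4.75-fold (log2 difference 2.25 ± 0.33, SE), and the carboxylesterase Ces2c and the aldehyde dehydrogenase Aldh1a1 rose 2.21-fold and 2.19-fold. In each of these 13 genes the 3 TCEP values lay above all 3 corn oil values.

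Other members of the same list did not pass. Cyp2c7 had a log2 difference of -0.16 ± 0.14 (SE), Cyp3a18 0.10 ± 0.30 (-0.01 with quantile normalization) and Cyp3a62 0.11 ± 0.24. The differences were 0.05 ± 0.18 for Ugt1a1, which conjugates bilirubin, 0.22 ± 0.19 for the export pump Abcc2, -0.03 ± 0.39 for the uptake carrier Slco1a4 and -0.40 ± 0.16 for Por, the electron donor of the cytochromes P450. Akr7a3 had a 2.83-fold higher mean, with corn oil values that varied by 1.18 log2 units (SD, 3 animals) and a log2 difference of 0.84 without corn oil replicate 2. Array probes of close paralogs, such as Cyp2b1 and Cyp2b2 or the Gstm genes, can share signal, so the separate values of such members are uncertain.

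**Figure D1:**
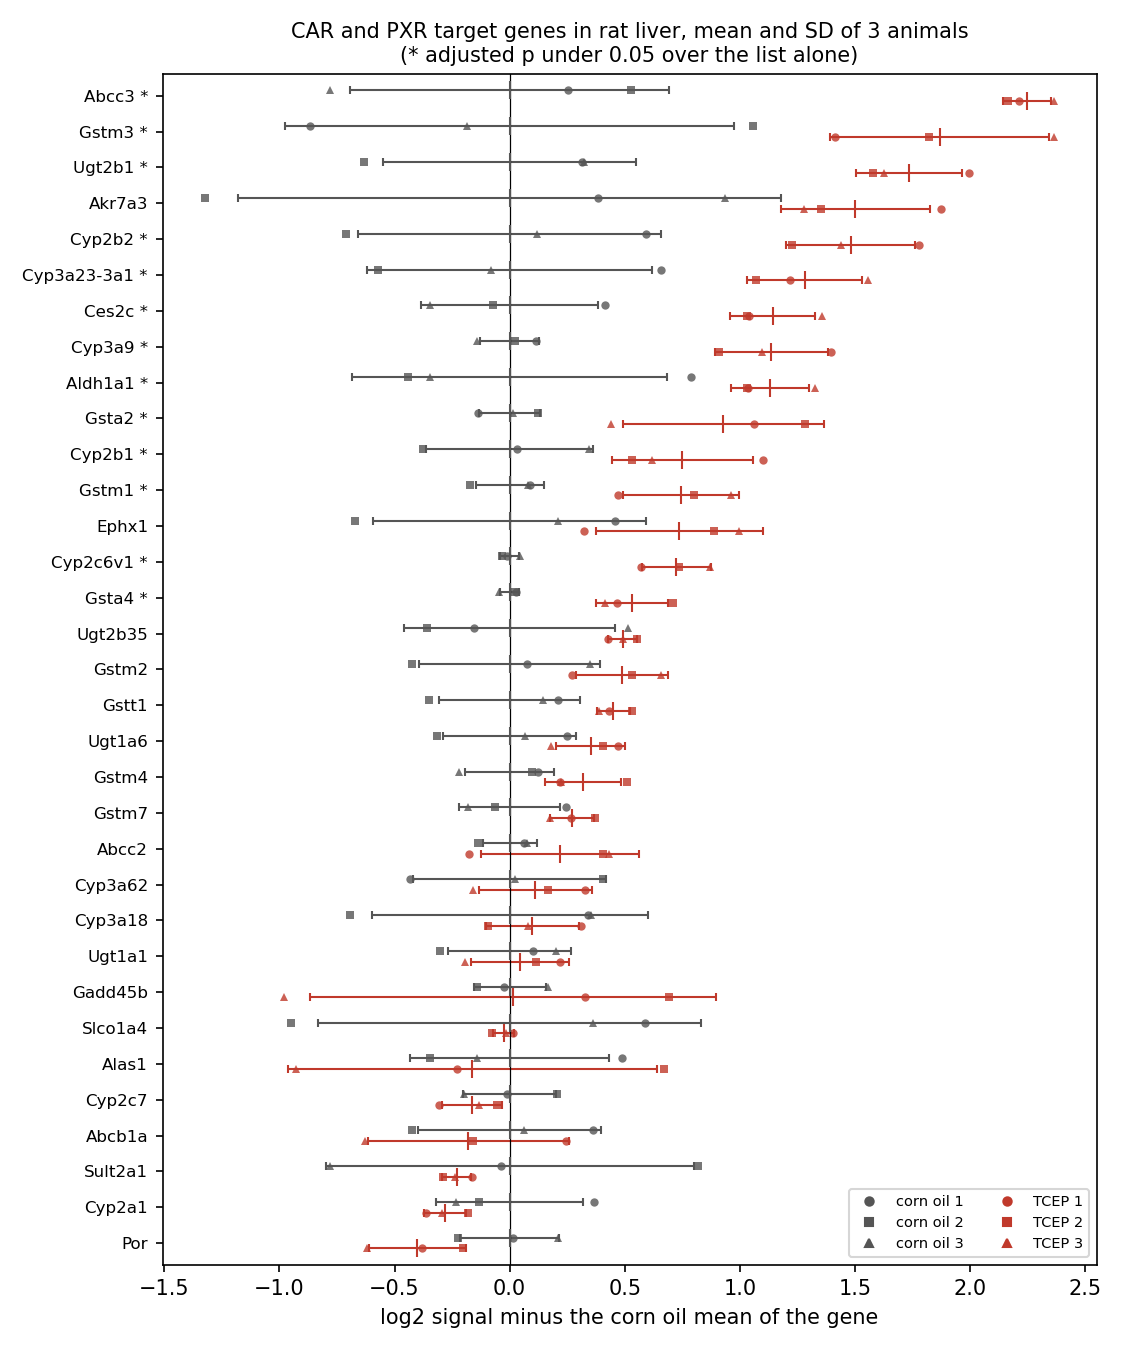
Log2 signal of the 33 measured CAR and PXR targets in each animal, minus the corn oil mean of the gene (x axis), for 3 corn oil (grey) and 3 TCEP (red) animals; ticks with bars give mean and SD, and asterisks mark adjusted p under 0.05 over the list alone. The TCEP points of the 13 marked genes lie to the right of all corn oil points, while Por and Cyp2a1 have TCEP means below those of corn oil.

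The shift of the CAR and PXR list against all other genes had an adjusted p of 1.39e-08 in limma's camera with a preset correlation between genes. With an estimated correlation camera gave an adjusted p = 0.932 (unadjusted p = 0.0301). The estimated correlation of the list was 0.117, against the preset of 0.01. Corn oil replicate 2, the only array scanned on a later day and alone on its slide, had a list median of -0.22 against the corn oil mean; within the first scan day, without that array, the median was 0.31 and 12 members passed over the list alone, 11 of them higher. The count of 13 was 7 without TCEP replicate 1, 8 without TCEP replicate 3, and 0 when the adjustment ran over the 608 members of all lists together. The 3 TCEP arrays shared a slide that held no corn oil array, so a random block for slide (13 members, median 0.48) does not separate that slide from the treatment.

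Acute phase proteins and their cytokine signalling genes had lower means with TCEP in 25 of 28 measured members, with a median log2 fold change of -0.22. The list was not split into members that rise and members that fall in an acute phase response. Its count and median therefore do not give the direction of that response. The list passed camera with the preset correlation (adjusted p = 0.00074) and not with an estimated correlation (adjusted p = 0.936). No member passed on its own, over all genes or adjusted over the list alone (0 higher, 0 lower). The abundant plasma proteins haptoglobin (Hp) and transferrin (Tf) had log2 differences of -0.23 ± 0.11 and -0.15 ± 0.09 (SE), and the protease inhibitor A2m had -1.07 ± 0.29. The call rested on corn oil replicate 2: within the first scan day, without it, the median was -0.08 and the adjusted p 0.327 (1.13e-06 to 0.969 over all alternatives).

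Across the whole array 0 of 27642 genes passed an adjusted p of 0.05 in limma, so 0 were called higher, 0 lower and 0 changed at least 2-fold; the smallest adjusted p was 0.29. At an unadjusted p under 0.05 there were 2552 genes, 1403 with a higher and 1149 with a lower mean in TCEP, where 1382 would arise with no difference. In 17.4% of the genes the 3 values of one group lay beyond all 3 of the other, against 10% by chance. The count of 2552 fell to 1610 without TCEP replicate 3. The share with a higher mean was 55% with scaling to the 75th percentile, 76.1% with centring on the median, 38.1% with no filter on dim probes and 46.4% without TCEP replicate 2.

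Because no gene passed, the largest differences are described for genes at an unadjusted p under 0.05, a criterion chosen after the values were seen; none of the fold changes in this paragraph passed the adjusted threshold over all genes. The highest TCEP to corn oil ratio among named genes was that of Acsm5, a mitochondrial medium-chain acyl-CoA synthetase, at 15.6-fold by its brightest probe (log2 5.69 ± 0.69 against 1.73 ± 0.61, SD, 3 animals per group). Its other probes gave log2 differences of 2.00 ± 0.41 and -0.60 ± 0.26 (SE), so the probes disagree in direction, and the mean over them gave 1.79. Higher means were also seen for the sorting nexin Snx10 (4.61-fold, log2 difference 2.20 ± 0.18), the imprinted noncoding RNA H19 (4.34-fold, 2.12 ± 0.31), the blood group transferase gene Abo3 (5.29-fold, 2.40 ± 0.48), the inflammatory caspase Casp12 (4.58-fold, 2.19 ± 0.67) and the transglutaminase Tgm4 (3.75-fold, 1.91 ± 0.66). Tmem116 had 3.51-fold. Abhd11-as1 had 5.63-fold and Zmynd12 3.46-fold, with corn oil signals well above background on only 1 and 2 of 3 arrays. Abcc3, Gstm3 and Ugt2b1 completed the 12 largest increases among genes with a symbol. With normexp background correction the log2 difference of Abhd11-as1 was 0.88, of Zmynd12 0.63, of Snx10 1.24 and of Casp12 1.37, and leaving out a corn oil array lowered that of Tgm4 to 1.18 (without corn oil replicate 2) and of Zmynd12 to 1.19 (without corn oil replicate 3).

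Among genes with a symbol, the 12 largest decreases were led by the alcohol dehydrogenase Adh6, 3.64-fold lower with TCEP (log2 difference -1.86 ± 0.38, SE), and by Popdc2, a membrane protein of striated muscle, 3.49-fold lower (-1.80 ± 0.51). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 3.33-fold lower (-1.74 ± 0.49), with TCEP values that varied by 0.96 log2 units (SD). Hsd17b6, a steroid dehydrogenase, was 2.63-fold lower (-1.39 ± 0.22), and the monocarboxylate carrier Slc16a11 2.86-fold lower (-1.52 ± 0.47). The neurotrophin Ntf3, the trefoil factor Tff3, the netrin receptor Unc5d and the potassium channel Kcnk5 had log2 differences of -1.48 ± 0.42, -1.34 ± 0.36, -1.34 ± 0.35 and -1.24 ± 0.40. Dim probes made up the rest: the olfactory receptor gene Or4g7 (-1.64 ± 0.46) and Chrdl1 (-1.49 ± 0.34) were well above background on 2 and 1 of 3 TCEP arrays. The phosphodiesterase Pde9a was well above background on 0 TCEP arrays, and its corn oil signal was at least 1.7-fold higher on the processed signal (adjusted p = 0.49); the same bound was 1.13-fold with normexp background correction. With that correction the differences of Or4g7, Chrdl1, Tff3 and Unc5d were -0.55, -0.31, -0.55 and -0.76, and the mean over probes gave -0.67 for Unc5d.

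**Figure D2:**
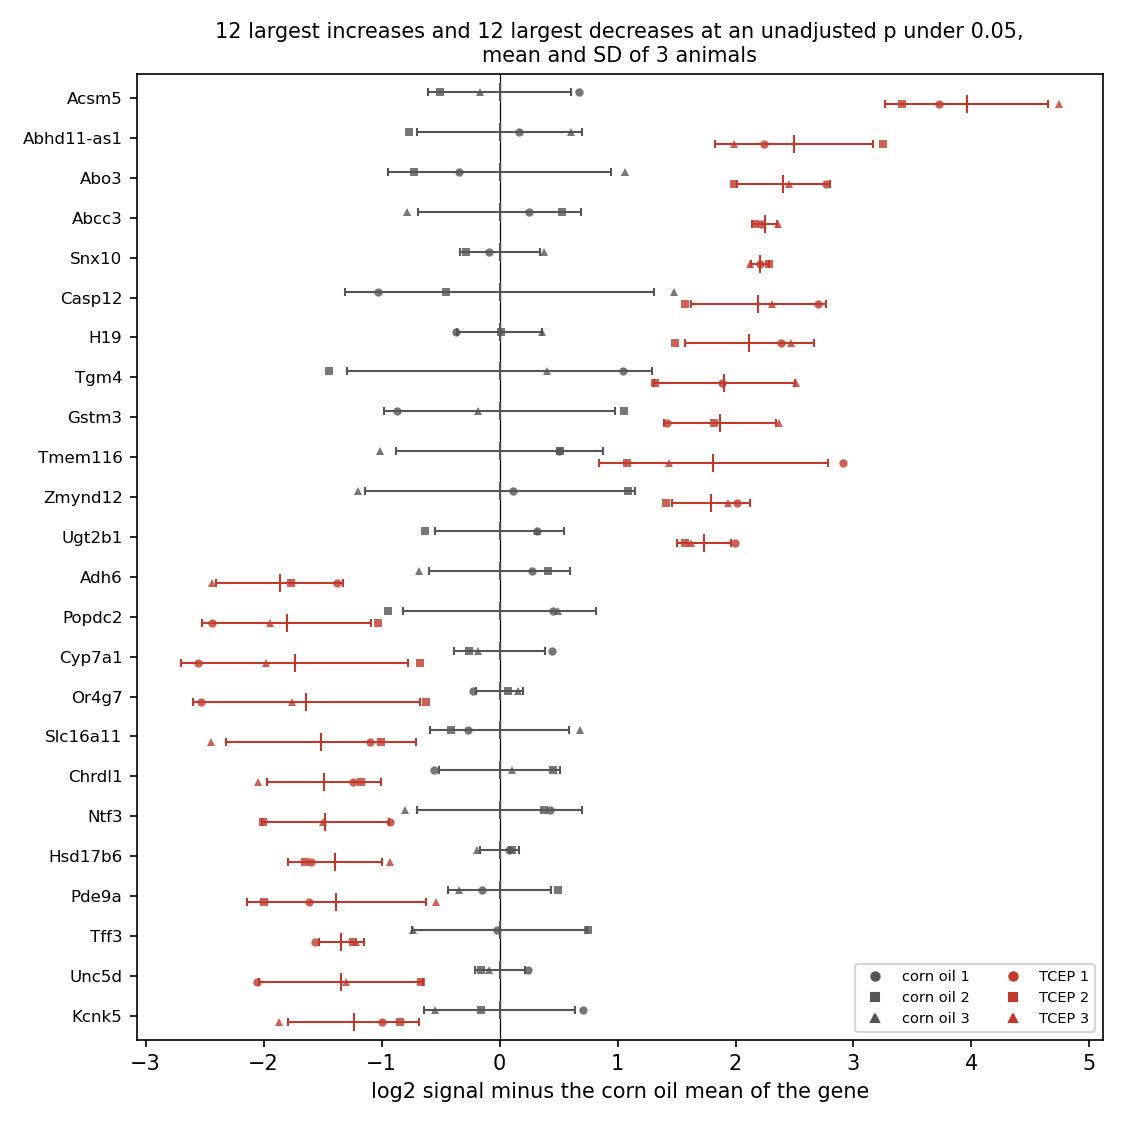
Log2 signal minus the corn oil mean of the gene (x axis) for the 12 largest increases and 12 largest decreases among genes with a symbol at an unadjusted p under 0.05, for 3 corn oil (grey) and 3 TCEP (red) animals; ticks with bars give mean and SD. Snx10 and Abcc3 have SDs of 0.08 and 0.10 among the TCEP animals, while Casp12 and Tgm4 have SDs of 1.31 and 1.29 among the corn oil animals.

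Several lists held 1 to 3 members that passed when adjusted over the list alone, while 0 members passed over all genes. In bile acid synthesis and transport 1 of 22 rose, Abcc3, and Cyp7a1 did not pass; the bright members Baat and Slc27a5, which conjugate and activate bile acids, had log2 differences of 0.09 ± 0.16 and -0.17 ± 0.16 (SE). Among 25 esterases and dehydrogenases 2 rose, Ces2c and Ces2h (1.51-fold), and 1 fell, Adh6, with Ces1c and Adh1c at 0.18 ± 0.11 and -0.43 ± 0.23. Of 20 genes of hepatocytes near the central vein, 1 fell: glutamine synthetase, Glul, was 1.85-fold lower (log2 3.27 ± 0.18 against 2.38 ± 0.20, SD, 3 animals per group), whereas Cyp2e1, of the same zone, had a difference of 0.09 ± 0.19 and Cyp1a2 -0.26 ± 0.19 (SE). Of 18 genes of hepatocytes near the portal tract 1 fell, Hsd17b6. Of 23 p53 targets 1 fell, the antiproliferative gene Btg2 (2.22-fold lower), and the cell cycle inhibitor Cdkn1a had -0.05 ± 0.11. Of 14 preneoplastic and fetal liver genes 1 rose, H19, while Gstp1, a marker of preneoplastic foci in rat liver, had 0.14 ± 0.09 and alpha-fetoprotein, Afp, -0.39 ± 0.23. Of 10 female-predominant genes 1 rose, Cyp3a9, although 9 had lower means with TCEP. No list in this paragraph passed camera at the settings of the main values. The portal-tract list passed as lower with quantile normalization and without corn oil replicate 2, TCEP replicate 1 or TCEP replicate 2, the esterase and dehydrogenase list as higher with no filter on dim probes and without corn oil replicate 1, and the female-predominant list as lower without corn oil replicate 3 (median -0.54).

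No member passed, over all genes or adjusted over the list alone, in the lists of other liver functions, and none of these lists passed camera at the settings of the main values. They covered 40 PPARalpha targets (median log2 fold change 0.06), 30 NRF2 targets (0.13), 26 cholesterol synthesis genes (0.06), 24 lipogenic genes (-0.02), 15 genes of glucose production (0.04), 31 genes of amino acid breakdown (0.01), 42 cell cycle genes (0.16), 31 endoplasmic reticulum stress genes (0.02), 17 heat shock genes (-0.15), 36 interferon-stimulated genes (0.01), 20 male-predominant genes (0.04) and 18 clock genes (-0.06). Leaving out 1 array changed the sign of each of these medians except those of the NRF2 and cell cycle lists. The cell cycle median still ran from 0.06 to 0.27 with 1 array left out. The PPARalpha, NRF2 and cell cycle lists passed camera as higher with no filter on dim probes, and with quantile normalization the cell cycle list passed as higher and the heat shock list as lower. With 1 array left out, the PPARalpha, cell cycle, heat shock, NRF2, cholesterol and interferon lists each passed in at least 1 fit. Bright members had small differences: 0.18 ± 0.13 (SE) for the peroxisomal thiolase Acaa1a, -0.15 ± 0.29 for Cyp4a2, 0.08 ± 0.10 for ferritin light chain Ftl1, -0.09 ± 0.33 for Hmgcs1, 0.04 ± 0.11 for Fbp1, -0.03 ± 0.12 for the chaperone Hspa5 and -0.19 ± 0.16 for Hspa8. Ccnd1, the cyclin that drives entry into the cell cycle, had -0.59 ± 0.38 (-0.91 without TCEP replicate 1 and -0.27 without TCEP replicate 2). Only 4 targets of the aryl hydrocarbon receptor were measured, too few for a list test, and Cyp1a1 was not well above background. For the lipogenic, bile acid, glucose, amino acid, interferon and male-predominant lists the median, the mean and the camera direction differed in sign.

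Markers of other cell types gave 0 members past the threshold, over all genes or adjusted over the list alone, and no such list passed camera at the settings of the main values. Macrophage markers had a median log2 fold change of -0.10 over 20 genes, neutrophil markers -0.20 over 6, T and NK cell markers -0.02 over 20, and B and plasma cell markers 0.47 over 9. Stellate cell, endothelial, cholangiocyte and erythroid markers had medians of -0.07, -0.04, 0.11 and -0.07 over 22, 16, 12 and 10 genes, and pancreas and adipocyte markers -0.18 and -0.15 over 7 and 6. With 1 array left out the stellate median ran from -0.11 to -0.03 and the cholangiocyte median from 0.04 to 0.21. The pancreas median ran from -0.25 to -0.10 and the adipocyte median from -0.22 to -0.03. The macrophage median was -0.43 without corn oil replicate 1, where the list passed camera as lower, and 0.14 without corn oil replicate 3. The neutrophil median was -0.45 without corn oil replicate 3 and 0.28 without corn oil replicate 2, and the T and NK cell, endothelial and erythroid medians also changed sign with 1 array left out. The B and plasma cell median was 0.22 without corn oil replicate 1, 0.13 with normexp background correction and 0.34 with no filter on dim probes, where the list passed camera as higher. The T and NK cell list (lower, without TCEP replicate 1), the erythroid list (lower, without corn oil replicate 3) and the cholangiocyte list (higher, without TCEP replicate 3) also passed.

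**Figure D3:**
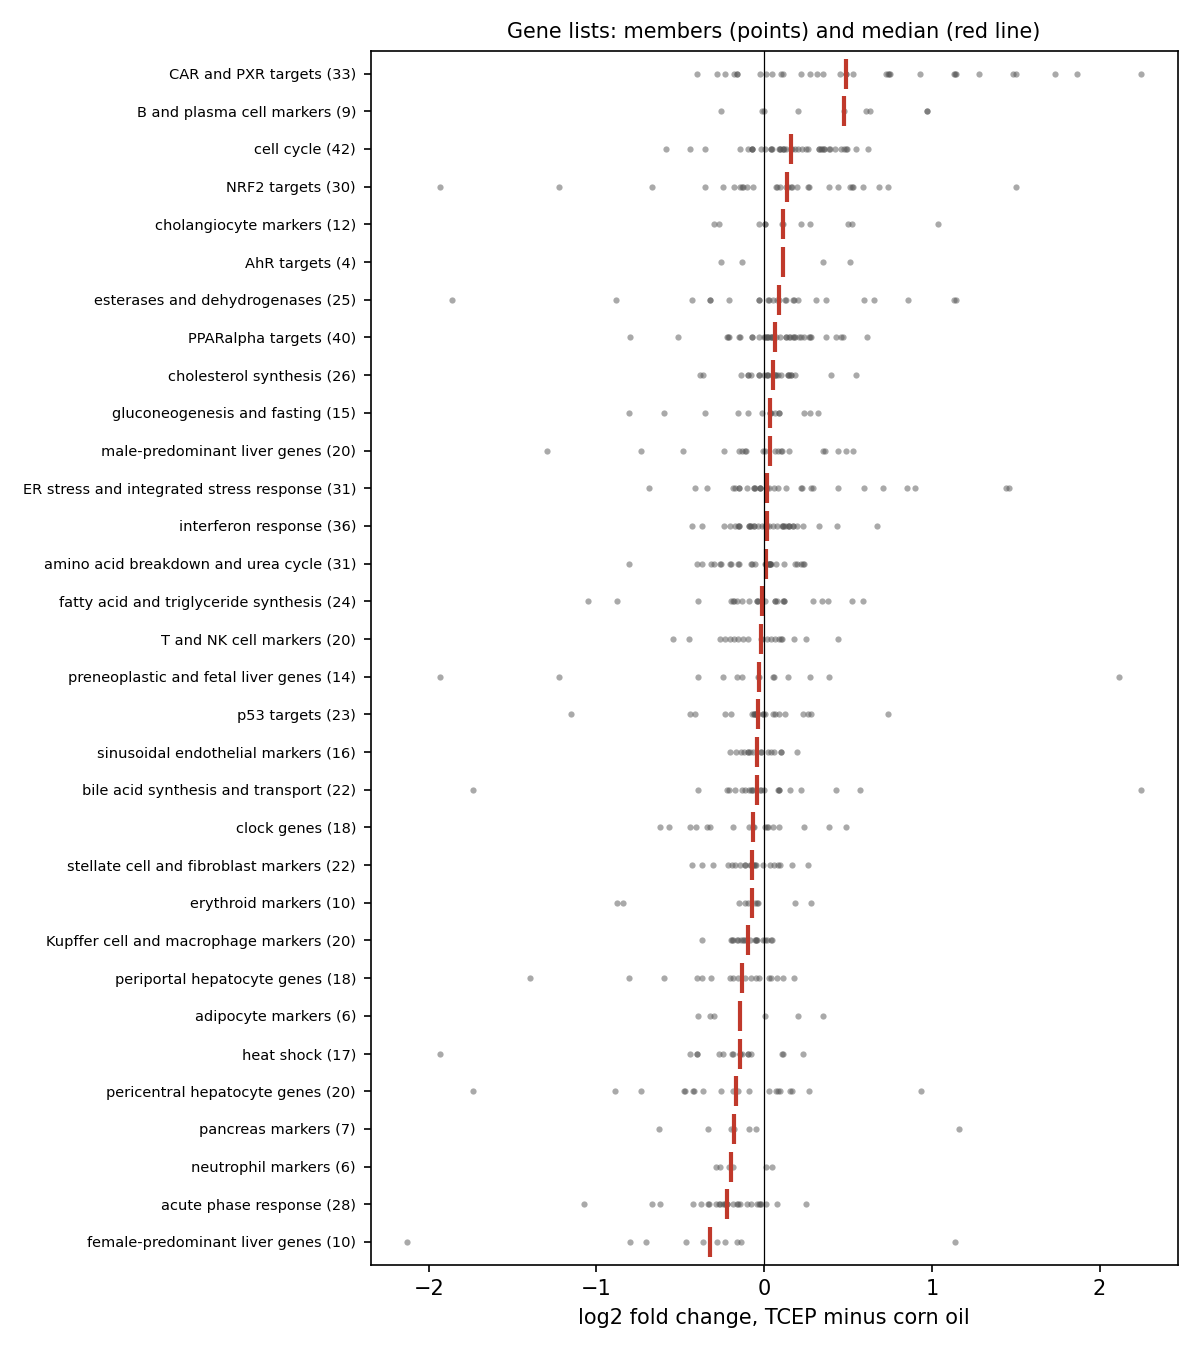
Log2 fold change (x axis, TCEP minus corn oil) of each measured member (grey points) and the median (red line) of 32 gene lists, with the number of measured members in parentheses. The median is 0.49 for CAR and PXR targets and -0.32 for female-predominant genes.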

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

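The adjustment over all lists together, the bound of Pde9a with normexp, and the alternatives for the unadjusted count and for the CAR and PXR members, were added after the data were seen. In all 18 alternatives run on genes, 0 genes passed the threshold; the smallest adjusted p ranged from 0.057 without corn oil replicate 3 to 0.716 without TCEP replicate 3. The count at an unadjusted p under 0.05 ranged from 1610 to 3221 when each array was left out. The 47 genes named in the text at an unadjusted p under 0.05 kept their direction in each alternative that gave a value. That was 17 alternatives for Abhd11-as1, Chrdl1, Or4g7, Pde9a and Zmynd12 and 18 for the others. Where the groups did not overlap, leaving out 1 array cannot change the direction. The 47 were also picked by their p on the same 6 arrays, so their kept direction is no independent support. Of the other 28 genes named, 11 changed direction in at least 1 alternative (Baat, Cdkn1a, Cyp2e1, Cyp3a18, Cyp3a62, Cyp4a2, Fbp1, Hmgcs1, Hspa5, Slco1a4 and Ugt1a1). Of these 28, 24 changed sign or moved by over 1.5 times with 1 array left out. Members of the CAR and PXR list past the threshold adjusted over the list alone numbered 7 to 12 with 1 array left out, and 0 adjusted over the 608 members of all lists. The number of lists past the threshold moved from 2 to 5 with quantile normalization, 7 with no filter on dim probes and 4 to 6 with 1 array left out. It was 0 both with an estimated correlation and with fry. The estimated correlations of the 2 called lists were 0.117 (CAR and PXR targets) and 0.334 (acute phase), far above the preset of 0.01. What moved the other counts was not tested. CAR and PXR targets were called higher in each camera run with the preset correlation, and of the 29 lists not called, 14 passed in at least 1 alternative. The interferon list, called in no direction with all arrays, passed as higher without TCEP replicate 2 (median 0.21), with medians of -0.15 to 0.21 over the arrays left out. With the replicate number as a block, 0 genes passed, 1896 had an unadjusted p under 0.05, 2 lists passed and 12 CAR and PXR members passed over the list alone. The numbers did not pair the animals: deviations from the group means correlated at -0.05, -0.16 and -0.02 for replicates 1, 2 and 3. Signal over background limits the dim genes: 57.2% of probes were well above it in corn oil replicate 2.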

Other observations

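The random-list tests on CAR and PXR targets, the family count and the slide and scan tests were chosen after the result was seen, as were the counts of splits for genes past the threshold, for lists and for immediate early genes; the immediate early list was tested as written beforehand. Immediate early genes, transcription factors and feedback regulators that are induced within minutes of a stimulus, had lower means with TCEP. Junb, Btg2, Nab2 and Socs3 had drawn attention with log2 differences of -1.19 ± 0.12, -1.15 ± 0.17, -0.89 ± 0.22 and -0.37 ± 0.11 (SE). A list of 40 other such genes was then written down without these 4, and 35 were measured. Of these, 27 had lower means with TCEP, among them Jun (-1.27 ± 0.53), Fos (-1.11 ± 0.67), Ccn1 (-1.05 ± 0.35) and Ier2 (-0.49 ± 0.18). The other 8 had higher means, by up to 0.80 ± 0.84. The values of the groups overlapped for Jun, Fos and Ccn1 and not for Ier2. Without corn oil replicate 1 the difference was -0.29 for Fos and -0.80 for Jun. No member passed adjusted over the list alone. Of the 17 measured heat shock genes, 14 had lower and 3 higher means. Hspa1a (-1.93 ± 0.73), with groups that overlapped, and Hsp90aa1 (-0.40 ± 0.16) were among the lower. The heat shock list (median -0.15) did not pass camera at the settings of the main values, and no member passed. With normexp background correction Hspa1a had -1.10, Fos -0.62 and Socs3 -0.22, and Ier2 had -0.30 without TCEP replicate 2 and Hsp90aa1 -0.25 without corn oil replicate 3.

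The median of the immediate early list was -0.36, below those of all 10000 random lists matched on mean signal (0% were lower, with the middle 95% from -0.07 to 0.09). The random lists were drawn gene by gene and lack the correlation of genes that vary together. They show a joint shift but cannot tell a group difference from variation between animals. The list was also written because 4 related genes were lower on these same arrays. Camera gave an unadjusted p of 3.04e-05 with the preset correlation and 0.00847 with an estimated correlation. On the same unadjusted scale, camera with an estimated correlation gave 0.0301 for the CAR and PXR list. Only 4 of the 35 also stand in a list fixed before the data were examined. The median per array, against the corn oil mean, was -0.06, -0.08 and 0.05 in the corn oil arrays and -0.23, -0.25 and -0.41 in the TCEP arrays. Leaving out each array gave -0.26 to -0.37, and the scaling alternatives gave -0.28 to -0.37. The 10 splits of the 6 arrays are too few for a share under 0.05; the real split gave an absolute median of 0.36, the highest in 1 of 10, and the highest other split 0.17. A candidate explanation for a joint shift of these genes is a difference between the groups in stress or handling around the time of killing; another is a lasting effect of TCEP. The labels give no order or time of sampling, so neither was tested. The TCEP arrays also lay alone on their slide, so a slide difference in these genes stays open as well.

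For the higher CAR and PXR targets, the tables argue against a brightness-dependent shift between slides. Of 10000 random lists matched on mean signal, 100% had a lower median than 0.49. The tables also argue against corn oil replicate 2 as the whole source. The median without it was 0.31, and the middle 95% of matched lists ended at 0.14 in the same fit. The 13 members past the threshold over the list alone came from 9 families, with Cyp2b and Cyp2c, for example, counted apart. The largest of these, Gstm, had 5 measured members, so 13 members could not have come from 1 family. The family count therefore does not test signal shared within a family. The matched lists were drawn gene by gene, so their range does not cover genes that vary together between animals. A slide difference specific to these genes stays open: the corn oil arrays on slide 1 exceeded the one on slide 2 by a median of 0.33 over the list, and the TCEP arrays lay alone on slide 3. The 10 splits are too few for a share under 0.05; the real split gave 13 members and a median of 0.49, each the highest in 1 of 10, and the highest other splits gave 0 members and 0.33. Induction by TCEP through CAR or PXR remains a hypothesis beside the slide.

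List calls by camera with the preset correlation were not specific to the real groups. All 10 splits gave at least as many lists as the 2 called with the real groups, though which lists these were was not compared. The highest other split gave 11, so such calls also arose in other groupings of the arrays. The other splits each mixed the groups unequally, so part of the difference between TCEP and corn oil remained in them. The preset of 0.01 lay below the estimated correlations of the 2 lists called with the real groups, 0.117 and 0.334. No test separated the low preset, animal, slide and scan day as the basis of the calls. The macrophage list, for example, had an estimated correlation between genes of 0.84 and passed as lower (median -0.43) without corn oil replicate 1. For genes past the threshold the splits decide nothing, since the real split gave 0, which all 10 reach; the highest other split gave 1. At an unadjusted p under 0.05 the real split gave 2552 genes, the highest in 1 of 10, and the highest other split 1702; 10 splits are again too few for a share under 0.05.

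Probes without a gene symbol also held large differences, and none passed the threshold. The unnamed probe C_CA_D0499 had a 12.1-fold higher mean with TCEP (log2 5.94 ± 0.66 against 2.34 ± 0.50, SD, 3 animals per group), close in size to the brightest Acsm5 probe (15.6-fold), while another Acsm5 probe had a log2 difference of -0.60 ± 0.26 (SE). The probe A_42_P738337, which the array design names by a sequence accession without a matched symbol, had an 8.06-fold higher mean (log2 difference 3.01 ± 0.79). Lower means were seen for A_42_P585695, 6.8-fold lower (-2.77 ± 0.36), and A_44_P434724, 6.4-fold lower (-2.69 ± 0.37), the latter well above background on 1 of 3 TCEP arrays. Both are likewise named by an accession without a matched symbol. These 2 probes ranked the 6 arrays in the same order, and whether they measure separate transcripts was not tested. With normexp background correction their log2 differences were -1.75 and -1.08.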
